A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

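RNA from 2 strains of S. pombe, with 2 libraries each, was depleted of rRNA, fragmented with RNase III, ligated to adaptors and sequenced on a SOLiD 4 instrument, per the labels' protocols. The submitters' processing notes name Bowtie 1.1.0, TopHat 1.4.1, SAMtools and Partek 6.0 without giving each a role. The genome build and annotation release are not given in the sources used here. Coordinates are therefore printed as the table gives them, with the end 1 base before its stop value.

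The deposited table holds 6808 features of 6807 genes. For each library it gives estimated counts of reads assigned to each feature by the authors, not normalized, of which 89.6% to 91.9% were whole numbers within 1e-06. The rest were fractions, found in 42.9% of features that overlap another on the same strand, in 0.883% of those that overlap on the opposite strand only and in 10.8% of those with no overlap. The deposited RPKM values, per the file headers, were reads scaled by transcript length and by the reads of the library. The deposited transcript length, per the file headers, is in bases. Junction RPKM and incompatible RPKM were deposited beside them. The deposited p-value and chi-square score per feature matched a chi-square with 3 degrees of freedom to within 1% for 99.5% of the nonzero p. There were 0 columns of values that could not be tied to a labelled library.

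Features were named from RefSeq's gene table of assembly ASM294v3, used for names only: 6649 of 6808 IDs matched (97.7%), and 4379 features have a symbol. The 38 mitochondrial features were named by a reciprocal overlap of at least 70% on the same strand with RefSeq's mitochondrial genes and carry the prefix mt-. Start positions of these differed by at most 121 bases, and 25 of 25 tRNAs named so carried the same amino acid.

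The estimated counts were rounded to whole numbers. The main comparison was edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr, and the quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided, with strain as the only term and a Benjamini-Hochberg adjusted p threshold of 0.05, over 5915 features that passed the filter. Levels are TMM-normalized CPM and log2 changes are those fitted by edgeR. Gene lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 26 lists. DESeq2 1.42.0 and limma-voom were run as alternatives, with camera run on the voom fit and its preranked form on DESeq2's Wald statistics. Shares of reads were compared by a two-sided exact permutation test, whose smallest p is 0.33 here. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.

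The lists, fixed before the data were examined, held other eIF3 subunits, nuclear electron transport genes, nuclear ATP synthase genes, protein-coding genes of the mitochondrial genome, mitochondrial ribosomal proteins, tricarboxylic acid cycle, glycolysis and fermentation, hexose transporters and glucose-repressed genes, core stress response, heat shock and chaperones, oxidative stress, iron uptake, phosphate and copper uptake, mating and nitrogen starvation, P-cell markers, meiosis and sporulation, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, amino acid biosynthesis, proteasome, histones, S phase, mitosis and cell separation, ergosterol, and Tf2 copies. Tests, alternatives and the rule for naming genes were fixed at the same time. The rule took int6, ura4 and leu1, then up to 12 genes in each direction past the threshold with both deletion libraries on the same side and a mean in the upper 75% of genes. Where fewer passed, those with the smallest p filled up to 6. From each list it took up to 4 members, up to 6 for the electron transport, stress and ribosomal protein lists, first by change among those past the threshold and then by level. Copies of Tf2, rRNA and tRNA were only summarised. Other genes named here were chosen after their values were seen.

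The edgeR and camera steps were tested on simulated data for this comparison, with 5915 features, 2 libraries per strain and a dispersion of 0.111, in 10 simulations of 200 changed genes. It recovered 5.67% of genes changed 2-fold, 63.6% of those changed 4-fold and 94.4% of those changed 8-fold, and 3.12% of its calls were false. Lists of 30 genes changed 1.5-fold were called in 10 of 10 simulations, and lists with no change in 0. Calls were made at an unadjusted camera p under 0.05. Genes were drawn independently with 1 common dispersion, whereas the ribosomal protein list had an estimated correlation of 0.596. These simulations therefore do not show how camera behaves on correlated lists. Recovery of single genes may also be lower here: int6, at a log2 change of −6.23, had an edgeR adjusted p of 0.111. The chi-square per degree of freedom between replicates was 125 for wild type and 275 for the deletion, so no pair looked like a library counted again.

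Library totals ran from 9926548 to 28254322 reads, and ura4 was not analysed here. Alternatives were the replicate number as a block, each library left out in turn, DESeq2 size factors, no filter on low counts, a stricter filter of at least 50 reads in each group mean, DESeq2's Wald test, limma-voom, nuclear protein-coding genes only, an added 2-fold minimum, a deposited p under 0.01 and shares outside nuclear rRNA. With a library left out, the lone library of its strain was taken to vary like the other strain. Added after the data were seen were the ribosomal list without the RNase P genes rpp1, rpp21 and rpp40, the hexose list without str3, and removal of the trends over GC content and transcript length from the edgeR statistics by loess before a camera test.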

Results

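RNA levels were measured in the fission yeast Schizosaccharomyces pombe, in wild-type cells and in cells in which int6, the gene of translation initiation factor subunit eIF3e, was disrupted with kanMX6, a drug resistance cassette. Both strains were of mating type h- and were grown in yeast extract medium, and rRNA-depleted total RNA was sequenced. There were 2 libraries of each strain. Features held 17485020 and 9926548 reads in wild-type replicates 1 and 2, and 28254322 and 16679123 reads in eif3e deletion replicates 1 and 2. Residual nuclear rRNA took 47.6% and 56.6% of the wild-type reads and 51.9% and 64.1% of the deletion reads. Protein-coding genes took 17.4% and 12% of the wild-type reads and 16.2% and 10.3% of the deletion reads. The median protein-coding gene had 170 and 61 reads in the wild-type libraries and 273 and 88 in the deletion libraries. Nothing in the labels says that the replicates came from separate cultures, so the spread between these libraries may be technical. The p-values of edgeR, DESeq2 and limma-voom for single genes rest on that spread. camera's p with the preset correlation compares the genes of a list with the other genes. A small value of it does not measure how closely the libraries of a strain match.

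The deleted gene was nearly free of reads in the libraries labelled as deletion. int6 (SPBC646.09c, chromosome 2, positions 938621 to 940366) held 504 and 194 reads in wild-type replicates 1 and 2, against 1 and 10 reads in deletion replicates 1 and 2. At 1 read, deletion replicate 1 stood at 0.128% of the wild-type mean CPM, with an exact 95% Poisson interval of 0.00323% to 0.711%. Deletion replicate 2 stood at 3.77% of that mean, with an interval of 1.81% to 6.93%. These intervals cover counting error only. The log2 change of int6 was −6.23 with a standard error of 0.93, and edgeR's quasi-likelihood test gave it an adjusted p of 0.111, short of the 0.05 threshold. Its log2 change was −6.15 without wild-type replicate 2, −4.71 without deletion replicate 1 and −9.35 without deletion replicate 2. Each of these fits holds 1 library of a strain and takes the spread from the other strain. They therefore do not settle whether int6 passes. leu1, which carries the point mutation leu1-32 in both strains, had 73 and 63 reads in wild type and 98 and 98 reads in the deletion, a log2 change of 0.06. ura4, whose removal is the other shared marker, was not analysed here.

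The series asked which mRNA levels differ between the strains. The siderophore-iron transporter gene str3 (SPAC1F8.03c, chromosome 1, positions 88201 to 90300) rose in the eif3e deletion. Its level was 4.72 ± 0.0006 CPM in wild type and 64.0 ± 17 CPM in the deletion (SD, n = 2). The wild-type values rest on 109 and 40 reads, and 2 nearly equal values do not measure precision. str3 had a log2 change of 3.76 with a standard error of 0.31 and an adjusted p of 0.0313 in edgeR's quasi-likelihood test. It was the 1 gene of 5915 past the threshold in that test, and 0 genes were lower. At an unadjusted p under 0.05 edgeR gave 284 higher and 314 lower genes. With the replicate number as a block, edgeR called 88 higher and 105 lower genes at an adjusted p under 0.05. The labels do not say what that number marks. DESeq2's Wald test called 49 higher and 41 lower genes at an adjusted p under 0.05, and limma-voom called 1 and 0. With a library left out, the lone library of its strain gives no spread, so the counts then rest on the other strain's replicates. edgeR's common dispersion was 0.144 and 0.148 without wild-type replicate 1 or 2. It was 0.0851 without either deletion replicate, against 0.111 with all libraries. More genes passed without a deletion replicate than without a wild-type one, so those passes do not show a firmer strain difference. str3 itself missed the threshold without wild-type replicate 1, at an edgeR adjusted p of 0.137 and a log2 change of 3.76, and its adjusted p over the settings tried, DESeq2 included, ran from 1.43e-18 to 0.137.

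Beside str3, the genes with the smallest p among those higher in both deletion libraries were rse1, mug15, tlh1, aca1 and gdh2, and none of these 5 passed the threshold. The RecQ-type helicase gene tlh1 lies at the very end of chromosome 1 (positions 1 to 5662) and has a near-identical copy, tlh2, with which its reads are partly shared. It measured 1.22 ± 1.11 CPM in wild type and 25.9 ± 2.93 CPM in the deletion (SD, n = 2). mug15 measured 1.03 ± 0.0468 CPM and 9.45 ± 0.386 CPM. gdh2, encoding the NAD-dependent glutamate dehydrogenase, measured 7.27 ± 1.72 and 43.6 ± 17.4 CPM. rse1, a non-coding RNA annotated as a repressor of the mating regulator ste11, measured 6.99 ± 0.212 and 32.8 ± 2.91 CPM. The acetyltransferase gene aca1 measured 4.68 ± 0.381 and 22.6 ± 5.51 CPM. The adjusted p in edgeR's test was 0.0814 for rse1 and mug15 and 0.111 for tlh1, aca1 and gdh2. Without deletion replicate 1 the log2 changes of these genes ran from 2.32 for rse1 to 4.77 for tlh1. Without deletion replicate 2 they ran from 2.01 for aca1 to 4.54 for tlh1, and without wild-type replicate 2 tlh1 stood at 5.88. A fit with 1 library of a strain takes its spread from the other strain, so it does not show whether they pass. rse1, aca1 and gdh2 overlap a feature on the opposite strand. How the counting treated strand is not given in the sources used here, so their levels are uncertain to that extent.

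Beside int6, the genes with the smallest p among those that the naming rule considers and that were lower in both deletion libraries were 3 non-coding RNAs and 2 protein-coding genes. None was past the threshold. SPNCRNA.1372 measured 24.2 ± 2.98 CPM in wild type and 4.75 ± 0.547 CPM in the deletion (SD, n = 2). SPNCRNA.785 had a log2 change of −1.53 and SPNCRNA.1382 one of −1.92. SPBPB10D8.02c, annotated as an arylsulfatase, measured 22 ± 2.22 and 6.28 ± 0.190 CPM, and SPAC18B11.09c, annotated with serine acetyltransferase activity, 32.8 ± 1.03 and 10.3 ± 2.24 CPM. Adjusted p in edgeR's test ran from 0.0814 for SPNCRNA.1372 to 0.164 for SPNCRNA.1382. Without deletion replicate 2 their log2 changes ran from −2.46 for SPNCRNA.1372 to −1.63 for SPNCRNA.785. Without deletion replicate 1 SPNCRNA.1372 stood at −2.23 and SPBPB10D8.02c at −1.84, and without wild-type replicate 2 SPNCRNA.1372 stood at −2.47. Such fits take the spread from the strain with 2 libraries, so they do not show whether these genes pass. All of these genes but SPAC18B11.09c overlap an opposite-strand feature. Both deletion libraries lay above both wild-type libraries for 1191 genes and below them for 1265, together 41.5% of the 5915 genes. The average over all ways to pair the 4 libraries is 33.3%. Genes are not independent, so this excess does not show that the libraries group by strain. In log2 CPM deletion replicate 2 correlated at 0.940 and 0.942 with wild-type replicates 1 and 2, and at 0.935 with deletion replicate 1. Deletion replicate 1 correlated at 0.926 and 0.904 with wild-type replicates 1 and 2, which correlated at 0.954 with each other.

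**Figure D1:**
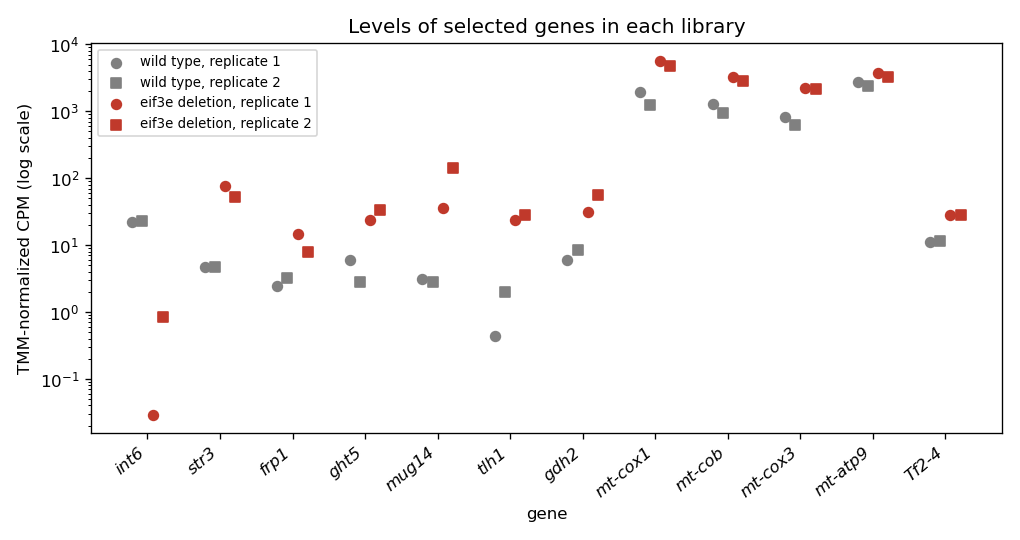
TMM-normalized CPM of 12 genes on a log axis, 1 point per library, with wild type in grey and the eif3e deletion in red, and replicate 1 as circles and replicate 2 as squares. int6 lies at 22.3 CPM on average in wild type and 0.435 in the deletion, while the other genes, picked for display after their values were seen, lie higher in both deletion libraries than in both wild-type libraries, of which str3 passed the threshold over all genes.

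The gene lists fixed before the data were examined asked whether functional groups moved together. The protein-coding genes of the mitochondrial genome rose as a group. All 8 were higher in both deletion libraries, with a median log2 change of 1.39. 0 of them passed the threshold over all genes tested, and 7 did when adjusted over the list alone, mt-atp9 being the exception. mt-cox1, a cytochrome oxidase subunit gene, measured 1599 ± 495 CPM in wild type and 5212 ± 693 CPM in the deletion (SD, n = 2). mt-rps3, the mitochondrial ribosomal protein gene, measured 2414 ± 47.8 and 7433 ± 967 CPM. The cytochrome b gene mt-cob measured 1121 ± 260 and 3028 ± 301 CPM, and mt-atp9, an ATP synthase subunit gene, 2599 ± 244 and 3473 ± 370 CPM. limma's camera with a preset correlation of 0.01 gave the list an adjusted p of 1.29e-07. The call was lost with an estimated correlation, with an adjusted p = 0.423. mt-cox1 and mt-cob overlap the intron-encoded genes annotated inside them on the same strand, so their reads are partly shared. mt-cob-I1, inside mt-cob, held 36194 and 45714 CPM in wild type and 34383 and 43803 CPM in the deletion, far above mt-cob itself. The rise of mt-cob may therefore depend on how reads were divided between these features. mt-cox1-I1b and mt-cox1-I2b, inside mt-cox1, had log2 changes of 2.13 and 2.35.

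The nuclear genes for the respiratory chain went the other way. The nuclear-encoded electron transport list fell, with 20 of 23 members negative, 9 lower in both deletion libraries and a median log2 change of −0.40. No member passed over all genes or adjusted over the list alone (0 and 0). qcr8, a subunit gene of the cytochrome bc complex, measured 224 ± 4.79 CPM in wild type and 150 ± 8.78 CPM in the deletion (SD, n = 2). Its partners qcr9 and qcr1 had log2 changes of −0.30 and −0.61, the cytochrome oxidase genes cox13 and cox7 −0.46 and −0.51, and the succinate dehydrogenase gene sdh1 0.34. camera gave an adjusted p of 0.0108 with the preset correlation and an adjusted p = 0.423 with an estimated correlation. Without deletion replicate 1 camera's adjusted p was 0.153, the highest of the settings tried, which ran from 0.00267. qcr8 overlaps a neighbour on the same strand, and qcr9 and atp18 overlap a feature on the opposite strand, which leaves their levels uncertain. The nuclear genes of ATP synthase also fell, all 13 being negative with a median of −0.37 and a camera adjusted p of 0.0288, again with an adjusted p = 0.423 under an estimated correlation. atp2 and atp15 had log2 changes of −0.34 and −0.37 and atp18 and atp16 of −0.03 and −0.01, and 0 members passed over all genes or adjusted over the list alone. The call for ATP synthase was lost without wild-type replicate 2, deletion replicate 1 or deletion replicate 2, at camera adjusted p of 0.109, 0.163 and 0.0504, and ran from 0.0102 to 0.163 over the settings tried.

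Iron uptake genes rose as a group. Of 12 members, 11 were positive and 9 were higher in both deletion libraries, with a median log2 change of 0.79. Only str3 passed over all genes, and 4 passed when adjusted over the list alone. These were str3, the vacuolar transporter gene abc3, and, named after their values were seen, the ferric reductase gene frp1 and the ferroxidase gene fio1. frp1 rose by 2.04, fio1 by 1.72 and abc3 by 0.97 on the log2 scale by that narrower test. abc3 overlaps a neighbouring gene on the same strand and pcl1 one on the opposite strand, so both levels are uncertain. The vacuolar iron transporter gene pcl1 had a log2 change of 0.16 and the ferrichrome synthetase gene sib1 one of 0.50. camera gave an adjusted p of 1.63e-05 with the preset correlation and an adjusted p = 0.423 with an estimated correlation.

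The list of hexose transporters and glucose-repressed genes rose with a median of 0.67 over 8 members and an adjusted p of 0.0241 in camera (adjusted p = 0.423 with an estimated correlation). str3 had been put in that list by mistake, although it is an iron gene, and without it camera's adjusted p was 0.226, the highest of the settings tried, which ran from 2.67e-05. The count over all genes was 1 higher, str3, and adjusted over the list alone 2 were higher and 1 lower. The others of these were the hexose transporter gene ght5, named after its values were seen, at 4.38 ± 2.19 CPM in wild type and 28.5 ± 6.30 CPM in the deletion (SD, n = 2), and the malic enzyme gene mae2, at 64.2 ± 12.9 and 33.8 ± 2.10 CPM. The paralogous transporter genes ght8 and ght2 had log2 changes of 0.17 and −0.44. The list also lost its call without wild-type replicate 2, at a camera adjusted p of 0.109, and without deletion replicate 2, at 0.170.

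Amino acid biosynthesis genes rose and ribosome biogenesis genes fell. In the amino acid list 42 of 51 members were positive and 23 were higher in both deletion libraries, with a median log2 change of 0.34. his4 measured 98.7 ± 0.00721 CPM in wild type and 207 ± 13.2 CPM in the deletion (SD, n = 2). The small wild-type SD is the closeness of 2 values and does not measure precision. eca39, the branched-chain aminotransferase gene, measured 103 ± 18.5 and 207 ± 84.8 CPM, and ilv3 and his2 had log2 changes of 0.24 and 0.28. camera gave an adjusted p of 2.25e-07, and an adjusted p = 0.608 with an estimated correlation. In the ribosome biogenesis list 62 of 67 members were negative and 43 were lower in both deletion libraries, with a median of −0.39. The rRNA methyltransferase gene nop2 measured 223 ± 8.96 and 137 ± 13.4 CPM, and nhp2, dip2 and utp4 had log2 changes of −0.37, −0.55 and −0.14. camera gave an adjusted p of 1.22e-08, and an adjusted p = 0.423 with an estimated correlation. his4 and eca39 overlap neighbours on the same strand, and ilv3, nop2 and dip2 overlap features on the opposite strand, which leaves their levels uncertain. In both lists 0 members passed over all genes and 0 when adjusted over the list alone. The wild-type replicates themselves differed on these lists, replicate 2 lying above replicate 1 by a median of 0.26 for amino acid synthesis and at −0.30 relative to it for ribosome biogenesis. Deletion replicate 2 lay above deletion replicate 1 by a median of 0.40 for amino acid synthesis, more than the strain difference of 0.34, and by 0.0014 for ribosome biogenesis.

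The other subunits of eIF3 fell slightly, with 9 of 10 negative and a median of −0.33. tif302, the eIF3b gene, measured 165 ± 12.9 CPM in wild type and 102 ± 1.78 CPM in the deletion (SD, n = 2), and sum1, the eIF3i gene, 144 ± 11.2 and 97.1 ± 0.167 CPM. tif310 and tif303 had log2 changes of −0.16 and −0.44, and 0 members passed over all genes or adjusted over the list alone. camera gave an adjusted p of 0.0264, and an adjusted p = 0.423 with an estimated correlation. Leaving out wild-type replicate 1, wild-type replicate 2, deletion replicate 1 or deletion replicate 2 ended the call, at camera adjusted p of 0.0612, 0.0598, 0.0857 and 0.138, within a range of 0.00729 to 0.138 over the settings tried. sum1 and tif310 overlap features on the opposite strand, so their levels are uncertain. Cytosolic ribosomal protein genes fell by a smaller amount, with 95 of 141 negative and a median of −0.10. rps21, rps1201, rps502, rps2401, rps23 and rpl4101, the most abundant members, had log2 changes of 0.15, −0.05, −0.51, −0.13, −0.24 and 0.02. camera's adjusted p was 0.0480, and an adjusted p = 0.813 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The direction turned without wild-type replicate 2, at a median of 0.16, and without deletion replicate 1, at 0.13. Replicate 2 lay above replicate 1 by a median of 0.436 in wild type and 0.456 in the deletion. Leaving out either library weights the deletion group towards replicate 2, so this shared gap can turn the direction by itself. Between libraries of the same number the median change was −0.124 and −0.054, though the labels do not say that the number marks a pair. With all libraries, camera on the limma-voom fit gave an adjusted p of 0.117. Most of these genes have near-identical paralogs, and rps502, rps23 and rpl4101 overlap opposite-strand features, so single members are uncertain.

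Copies of the retrotransposon Tf2 rose. All 13 were higher in both deletion libraries, with a median log2 change of 1.32 and a camera adjusted p of 1.30e-13 (adjusted p = 0.423 with an estimated correlation). None passed over all genes (0), and 13 did when adjusted over the list alone. The copies are near-identical and share reads, so that they are not 13 independent measurements. Ergosterol synthesis genes rose with 17 of 21 positive, a median of 0.28 and a camera adjusted p of 0.0288 (adjusted p = 0.606 with an estimated correlation). erg10, erg7, erg9 and the sterol sensor gene scp1 had log2 changes of 0.28, 0.44, −0.14 and −0.36, and 0 members passed over all genes or adjusted over the list alone. The ergosterol call was lost without wild-type replicate 1, at a camera adjusted p of 0.172, and without deletion replicate 2, at 0.208, within a range of 0.0116 to 0.208 over the settings tried. erg9, erg10, erg7 and scp1 overlap opposite-strand features and scp1 also a same-strand one, so these levels are uncertain.

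The core stress response list was not called. Of its 34 members 17 were positive and 17 negative, with a median log2 change of 0.00083 and a camera adjusted p of 0.727. No member passed over all genes (0), and 1 was higher when adjusted over the list alone, mug14, named after its values were seen, at 2.97 ± 0.202 CPM in wild type and 89.9 ± 77.2 CPM in the deletion (SD, n = 2). The glutathione transferase gene gst2 and the glycerol phosphate dehydrogenase gene gpd1 had log2 changes of 1.62 and −0.78, and plr1, rad24, uba1 and hsp9 of 0.09, 0.28, 0.01 and −0.63, where rad24 overlaps an opposite-strand and hsp9 a same-strand feature and both are uncertain. The median was −0.09 without wild-type replicate 2, −0.16 without deletion replicate 1 and −0.12 without deletion replicate 2. camera's own direction turned without wild-type replicate 2, at an adjusted p of 0.855 within a range of 0.352 to 0.978 over the settings tried.

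**Figure D2:**
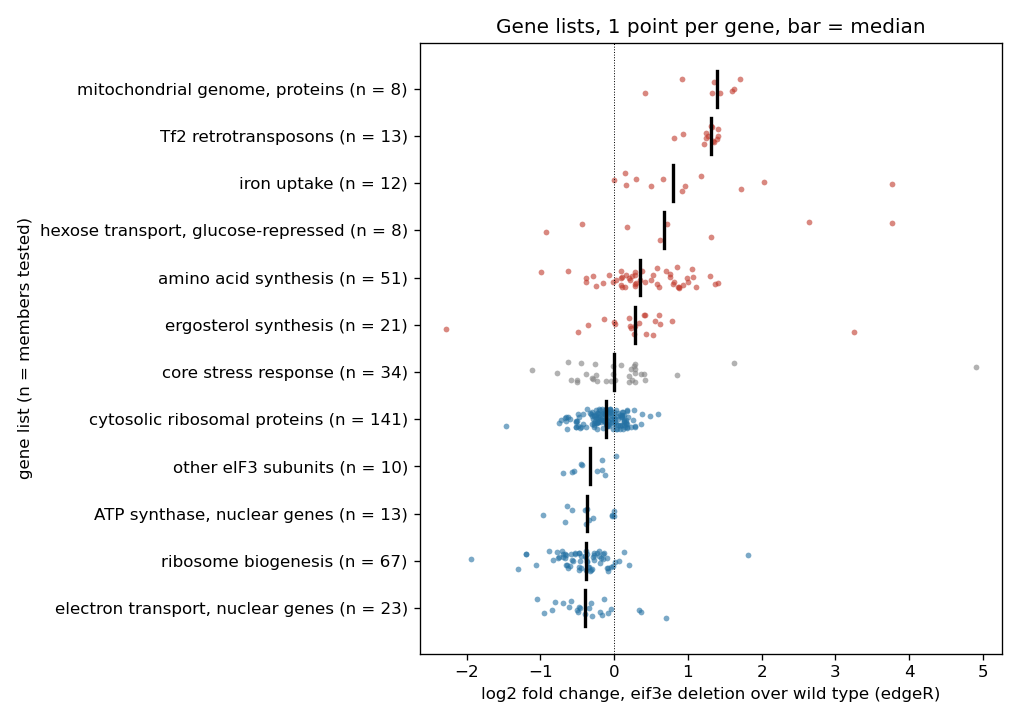
Log2 fold change of each gene in 12 lists, deletion over wild type, with 1 point per gene and a black bar at the median. Red lists were called higher and blue lists lower by camera with the preset correlation of 0.01, and the grey list, the core stress response, was not called. The hexose list is shown with str3, put in it by mistake, and was not called without it. With estimated correlations camera called 0 of the 26 lists tested. The medians run from −0.40 for nuclear electron transport genes to 1.39 for mitochondrial protein genes.

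No other list passed in camera, and in these 14 lists 0 members passed over all genes and 0 when adjusted over the list alone. Enzymes of the tricarboxylic acid cycle had a median log2 change of 0.36 and an adjusted p of 0.0598, phosphate and copper uptake genes 0.39 and 0.0811, glycolysis and fermentation genes 0.29 and 0.133, and proteasome genes 0.14 and 0.133. For histone genes the median was −0.26 and for S-phase genes −0.24, both with an adjusted p of 0.246. For P-cell markers, which h- cells should lack, it was 0.25 with an adjusted p of 0.349 over 3 tested genes, and for oxidative stress genes 0.17 with 0.535. For translation factors outside eIF3 it was −0.07 with 0.638, for heat shock genes and chaperones 0.0075 with 0.672, and for mitochondrial ribosomal proteins 0.08 with 0.727. Some of these passed camera with a library left out. Tricarboxylic acid cycle genes did so without wild-type replicate 2 (adjusted p of 0.0116) and without deletion replicate 1 (0.00396), within a camera range of 0.00396 to 0.590 over the settings tried. Glycolysis genes did so without deletion replicate 1 (5.54e-05, the range being 5.54e-05 to 0.549), phosphate and copper genes without wild-type replicate 2 (0.00905, range 0.00905 to 0.491) and proteasome genes without deletion replicate 2 (0.0309, range 0.0309 to 0.777). Mating and nitrogen starvation genes had a median of 0.16, a mean of −0.12 and an adjusted p of 0.727. Genes of meiosis and sporulation had a median of −0.03 and a mean of −0.11 with an upward camera statistic and an adjusted p of 0.931, and genes of mitosis and cell separation a median of 0.06 and a mean of −0.03 with a downward one and 0.904. In all, camera called 6 of 26 lists higher and 5 lower with the preset correlation and 0 with estimated correlations. Among the 6 is the hexose list, which held str3 by mistake and had a camera adjusted p of 0.226 without it. The smallest unadjusted camera p with an estimated correlation was 0.0416, for iron. Yet for iron, electron transport, ATP synthase and eIF3 the estimated correlation (0.0064, −0.015, −0.038 and −0.094) lay below the preset 0.01. Their camera p rose all the same, so correlation among members does not account for those losses. With 2 libraries per strain, 0 calls with estimated correlations does not decide whether these lists moved. limma's fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 1 list, the eIF3 subunits, at an adjusted p of 0.0192.

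Classes of RNA were compared as shares of all reads. snoRNAs took 5.90% ± 0.803 of reads in wild type and 4.19% ± 0.249 in the deletion (SD, n = 2), nuclear tRNAs 5.39% ± 1.5 and 3.51% ± 0.439, and non-coding RNAs 6.75% ± 0.505 and 5.73% ± 0.243. As shares of all reads these were lower in both deletion libraries, with an exact permutation p of 0.33, the smallest that 2 against 2 libraries can give. Mitochondrial tRNAs took 1.32% ± 0.0199 and 1.07% ± 0.0957 of all reads, with an exact permutation p of 0.33. This share sums reads, so the features with most reads weigh most. Over single features in TMM-normalized CPM the median log2 change was 0.80, with 9 of 25 higher in both deletion libraries and 1 lower. That median does not show that mitochondrial tRNA rose in total. As shares of reads outside nuclear rRNA, snoRNAs stayed lower in both deletion libraries, at 12.4% and 12.3% in wild type and 9.08% and 11.2% in the deletion. On that scale the strains overlapped for nuclear tRNAs (8.28% and 14.9% in wild type, 6.66% and 10.6% in the deletion), non-coding RNAs and mitochondrial tRNAs, with exact permutation p of 0.667, 1 and 0.667. Mitochondrial rRNA and the other mitochondrial features were then higher in both deletion libraries, each with an exact permutation p of 0.33. For protein-coding genes, nuclear rRNA, snRNA, mitochondrial rRNA and the other mitochondrial features the libraries of the strains overlapped as shares of all reads, with an exact permutation p of 0.667.

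The authors' deposited table gives a chi-square p for each feature, under 0.05 for 6175 features, or 90.7%. Its values match a chi-square with 3 degrees of freedom across the 4 libraries, so it tests whether any library differs, not whether the strains do. str3 was among the features under 0.05 in the authors' deposited table.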

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

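The tests reported here were chosen, or revised, only after results had been seen, except that the prediction for GC content and length was written before its result. Junction reads, which no comparison above uses, were a larger part of the deletion libraries. Junction RPKM made up 3.75% and 4.09% of RPKM in wild-type replicates 1 and 2 and 4.19% and 4.60% in deletion replicates 1 and 2 over 2486 spliced protein-coding genes. The deletion mean was 4.40%, and both deletion libraries lay above both wild-type libraries, which has an exact permutation p of 0.33 at best with 2 libraries per strain. The share of these genes with any junction signal did not separate the strains (60.3% and 45.2% in wild type, 53.2% and 51.8% in the deletion).

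Mitochondrial mRNAs were higher in the deletion by a median of 1.39 on the log2 scale. An equal rise of all mitochondrial RNA, including one from scaling, would leave the ratios between mitochondrial RNAs as they were, and the measures of this did not all exceed the gap between replicates. The log2 ratio of summed mRNA reads to mitochondrial rRNA reads was 0.881 higher in the deletion (largest gap between replicates 0.437), and that to mitochondrial tRNA reads 1.45 higher (gap 0.880). Over features the median mRNA rose by 0.869 more than the median rRNA (gap 0.403) but by 0.713 more than the median tRNA, within a gap of 1.35. That gap ran the same way in both strains, replicate 2 against replicate 1 being −1.35 in wild type and −1.09 in the deletion. Between libraries of the same number the difference from tRNA was 0.583 and 0.842, though the labels do not say that the number marks a pair. With the intron reading frames in the sum, mostly mt-cob-I1, the ratio to rRNA changed by −0.0373 (gap 0.103). mt-cob-I1 had a log2 change of −0.067, while mt-cox1-I1b and mt-cox1-I2b had changes of 2.13 and 2.35. That ratio therefore averages unlike changes, and its small size does not show an equal rise. An equal rise, uneven depletion or recovery of rRNA and tRNA between libraries, which was not tested, and an effect of the eIF3e loss on these mRNAs may each contribute.

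Amino acid synthesis genes were higher and ribosome biogenesis genes lower. Removing the trends over GC content and transcript length left both lists called by camera with the preset correlation of 0.01, the larger adjusted p being 8.46e-06, which argues against those trends as the whole cause of that call. With estimated correlations and no correction, neither list was called (adjusted p of 0.608 and 0.423). Variation of growth state between cultures stays open: the score of the amino acid list minus the ribosome biogenesis list differed between strain means by 0.839, which is 1.972 times the larger gap between replicates. That gap was alike in both strains (replicate 2 above replicate 1 by 0.426 in wild type and 0.422 in the deletion), so the ratio decides little, and a growth state that differed between the strains' cultures cannot be told apart from an effect of the deletion, since growth was not measured here and there are 2 libraries per strain.

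Tf2 copies were higher by a median of 1.32. Sharing of reads among the copies can move reads between copies but not change their sum, and the summed reads rose by 1.241 on the log2 scale, against a largest replicate gap of 0.296. The log2 ratio of summed Tf2 reads to summed protein-coding reads, which no scaling can move, was 1.228 higher in the deletion, against a largest replicate gap of 0.210, which argues against scaling. Higher Tf2 transcription and more Tf2 copies in the deletion strain were not tested against each other, and both may account for the difference.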

How the results depend on the processing

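The tests with GC and length trends removed and with list members removed were chosen after the data were seen, and the others before. str3 was called in every setting but without wild-type replicate 1, and the iron, mitochondrial genome, Tf2, amino acid and ribosome biogenesis lists kept their direction and their call by camera at the preset correlation in each of these settings run on them, while with estimated correlations, and by fry, none of these lists was called. The GC correction is void for the mitochondrial genome list, of which 0% has a GC value, and it moved the hexose and ergosterol lists from a camera adjusted p of 0.0355 each to 0.0570 and 0.0659. Their median statistics went from 1.29 (SD 2.36) to 1.21 (SD 2.37) and from 0.936 (SD 1.21) to 0.772 (SD 1.21). Both calls lay near the threshold before the correction, and why they ended was not tested. The 2-fold minimum, added to the unblocked edgeR test of all 4 libraries only, changed neither of its counts. Counts of higher and lower genes were 15 and 5 with no filter, 9 and 2 among nuclear protein-coding genes and 49 and 41 with DESeq2's Wald test, and ranged over 0 to 70 and 0 to 172 with a library left out (0 and 0 without wild-type replicate 1, 7 and 4 without wild-type replicate 2, 33 and 17 without deletion replicate 1, 70 and 172 without deletion replicate 2). The cause was not tested. Beside int6, 54 named genes were followed. DESeq2 size factors left each of these and each of the 26 lists on its side of the threshold with its direction, and limma-voom did so for 21 lists and 53 genes. Genes that newly passed numbered 14 with DESeq2's Wald test, 7 with no filter and 5 among nuclear protein-coding genes. List calls were lost for eIF3, ATP synthase and ergosterol with DESeq2's Wald test, for ergosterol among nuclear protein-coding genes and for hexose with the stricter filter and limma-voom, and gained for the tricarboxylic acid cycle with no filter and for phosphate and copper with the stricter filter and limma-voom. Replicates share only a number and a title code across the strains. With the replicate block 88 genes were higher and 105 lower, 16 of the named genes newly passed, 14 lists were called and int6 stood at −6.35 with an edgeR adjusted p of 0.00315, and the within-strain differences of the numbered libraries correlated at 0.238 over genes. Between libraries of the same number, the score of the amino acid list minus the ribosome biogenesis list was 0.841 and 0.838 higher in the deletion. Depth limits the low genes most, the median protein-coding gene holding 61 reads in wild-type replicate 2.

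int6 passed the threshold at −6.23 with no filter, −5.75 with DESeq2's Wald test and −6.30 among nuclear protein-coding genes. With a library left out its log2 change ranged from −9.35 to −4.71 (−6.15 without wild-type replicate 2, −4.71 without deletion replicate 1 and −9.35 without deletion replicate 2). DESeq2's Wald test called 7 lists and limma-voom 10, and 8 to 9 were called with a library left out. The ribosomal protein list missed the threshold with no filter (−0.10), the stricter filter (−0.0871), limma-voom (−0.0919) and DESeq2's Wald test (−0.11), and ranged from −0.36 to 0.16 with a library left out, turning without wild-type replicate 2 and deletion replicate 1. It kept its call without the RNase P genes (−0.11). The electron transport list ranged from −0.60 to −0.31, missing the threshold without deletion replicate 1. The core stress list ranged from −0.16 to 0.14, and its median statistic was −0.0238 after the GC correction. Lists not called at first passed in some settings: tricarboxylic acid cycle without wild-type replicate 2 (adjusted p 0.0116) and deletion replicate 1 (0.00396), glycolysis without deletion replicate 1 (5.54e-05), phosphate and copper without wild-type replicate 2 (0.00905), and proteasome without deletion replicate 2 (0.0309).

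Shares outside nuclear rRNA moved the strain difference to 3.95 points for other mitochondrial features, 1.89 for mitochondrial rRNA and −0.153 for non-coding RNA. Directions also turned for values near 0 that no setting called. These were leu1 with the block (−0.0136) and limma-voom (−0.0462), atp16 with the stricter filter (0.0062), rpl4101 among nuclear protein-coding genes (−0.0159), the mating list with DESeq2 (0.15, by its test statistic) the meiosis list with no filter (−0.0364) and limma-voom (−0.0289), and the cell separation list with limma-voom (0.0934), likewise by the test statistic. With a library left out the medians ranged over 0.0017 to 0.18 for mitochondrial ribosomal proteins, −0.11 to 0.63 for glycolysis, −0.0613 to 0.10 for heat shock, 0.0477 to 0.40 for mating, −0.41 to 0.54 for P-cell markers, −0.11 to 0.35 for meiosis, −0.15 to 0.0866 for translation factors and −0.17 to 0.18 for cell separation. The genes ranged over −0.87 to 0.78 for leu1, −0.53 to 0.36 for tif310, −0.87 to 0.10 for cox13, −0.0163 to 0.65 for sdh1, −0.28 to 0.18 for atp18, −0.29 to 0.23 for atp16, −0.12 to 0.46 for rps21, −0.48 to 0.28 for rps1201, −0.46 to 0.30 for rps2401, −0.57 to 0.16 for rps23, −0.20 to 0.26 for rpl4101, −0.0817 to 0.52 for ilv3 and −0.34 to 0.0838 for erg9. The causes were not tested.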

Other observations

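The tests in this part were chosen after results had been seen. Nuclear tRNA features had a median log2 change of −0.90, and 45 of 135 were lower in both deletion libraries and 0 higher. Over all genes 41.5% were higher or lower in both deletion libraries. None of the tRNA features passed the threshold (0). As shares of reads outside nuclear rRNA, nuclear tRNAs took 8.28% and 14.9% in wild type and 6.66% and 10.6% in the deletion, so the strains overlapped. A general fall of tRNA is therefore not shown. Of 46 snoRNA features 27 were lower and 4 higher, with a median of −0.52. The deposited incompatible RPKM, of reads that overlap a gene but not its transcript model, summed to 30.2 and 28.6 in the wild-type libraries and 56.6 and 27.8 in the deletion libraries. Open reading frames inside mitochondrial introns did not move alike. The one in mt-cox1-I2b measured 337 and 297 CPM in wild-type replicates 1 and 2 and 2030 and 1203 CPM in deletion replicates 1 and 2, while mt-cob-I1, at 36194 and 45714 CPM in wild type and 34383 and 43803 CPM in the deletion, had a log2 change of −0.07.

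The helicase gene tlh2, on chromosome 2 at positions 4526885 to 4532899, had 1 and 5 reads in the wild-type libraries and 153 and 46.2 in the deletion libraries. The neighbouring uracil-regulated genes urg1 and urg2 differed between replicates more than between strains. urg1 measured 2.34 and 61.2 CPM in wild-type replicates 1 and 2 and 0.741 and 6.73 CPM in deletion replicates 1 and 2, and urg2 1.51, 43.4, 0.114 and 6.23 CPM in the same order.

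The high tlh1 level raised the hypothesis that genes within 100 kb of the ends of chromosomes 1 and 2 move as a set. Over 63 such protein-coding genes the median log2 change was −0.25, against 0.04 for the other 4722, and limma's camera gave a p of 0.123, so no shift of the set was detected, and a smaller one than the design can show stays open. A second hypothesis was that genes with introns move against those without. The median was 0.04 for 2388 genes with introns and 0.03 for 2397 without, and camera gave a p of 0.946, which gives no support to such a shift.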
